A study of Danio rerio with 5 samples.

How the data were processed

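The files were 5 lists of H3K9ac regions from zebrafish embryos at 36 hours post-fertilisation, 3 from sinhcaf mutants and 2 from wild-type embryos. Groups and replicate numbers were taken from the labels. Per the file headers, each library was called on its own with MACS 2.1.0.20150731 in broad mode, with no control library, a p cut-off of 1e-05 for strong and 0.1 for weak regions, a band width of 200 bp, a fragment length of 196 bp, tags of 50 bp, at most 1 tag per position and a local background over 10000 bp. The effective genome size in the headers is 3.72e+10 bp, far above the 1345 Mb that the lists span on the 25 chromosomes. GRCz11, bedtools and HOMER 4.10.3 are named in the submitters' processing notes. The aligner is not given in the sources used here.

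Per the file headers, the columns are the pileup of a region (a coverage signal in tags of that library), its −log10 p-value, its fold enrichment and its −log10 q-value, all as the authors deposited them. The headers say that q-values were not calculated, but the deposited column holds values, so the q-value was not used here. These values are the authors' own. They were used only to rank or filter regions within a list and to check the lists, since scores of lists called separately cannot be compared. No tag counts on common regions were used here, so no count test applied. Depth after removal of duplicates was 10744373, 11395261 and 11200601 tags in the mutant and 11077536 and 10902561 in the wild type.

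Before the data were examined, the tests, the alternatives, 18 gene lists and a rule for named genes were fixed. The plan tested promoters and genes. It could not be followed there, because no annotation of GRCz11 was used here, and positions from another build were not converted. Genes with a promoter peak, the gene lists and the sinhcaf locus were therefore not analysed here. The covered length at promoters was replaced by covered bases in 4 kb windows over the 25 chromosomes, and shares by annotation class by shares by chromosome. The rule named, in each direction, the 12 stretches of adjacent called windows with the largest change and no overlap between genotypes. All leading windows tied in size, so the tie was broken by length, a choice made after the data were seen. The division by long stretches, the limit of 10 kb for a long stretch (limits of 20 and 50 kb were also tried), the counts on alternate contigs and the look at chromosome 4 were also chosen after the data were seen.

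Regions of all lists sharing at least 1 bp were merged, and presence was counted per list. Counts were set beside all 10 splits of the 5 libraries into 3 and 2. A long stretch was a called region or a gap between neighbouring regions longer than 10 kb. A stretch of 1 genotype was at least 5 kb long, lay in a long stretch of every list of that genotype and in none of the other. Differences in means were tested with exact two-sided permutation tests. Covered bases per window were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust, Benjamini-Hochberg adjustment, threshold 0.05, two-sided). Windows wholly covered or wholly empty in every list of a genotype have no spread there, and limma offset very small variances from 0, so the standard errors of such windows come from the other windows. The span of the called regions on an alternate contig was placed on the chromosome its name gives, by the numbering of the files. That both share 1 numbering was taken from the data and is not stated in a label.

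Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The presence count was tested on simulated data and returned 200 of 200 and 150 of 150 planted regions, and the stretch code 25 of 25 and 15 of 15. For limma on regions up to 10 kb outside long stretches, 252342 windows were simulated. With 27346 windows changed, 5.80%, 48.4% and 88.4% of those shifted by 1000, 2000 and 3000 bp were recovered and 4.83% of the calls were false. With 200 changed windows among 333268 and all regions in use, 6.06% of those shifted by 3000 bp were recovered beside 948 false calls, which made up 99.6% of the calls. In these simulations residuals were shuffled within each window. They were first drawn with replacement, which can repeat a residual within a genotype, and the scheme was changed after its result was seen. Drawn with replacement, the comparison of all regions gave 5245 false calls (98.5% of the calls) and recovered 65.2% of the windows shifted by 3000 bp. That outside long stretches with 27346 changed windows gave 16.7% false calls, and with 200 changed windows it recovered 0%. Alternatives were other sets of regions by score, width or place, a larger overlap, other windows and model settings, each library left out, and a fit with the replicate number as a block.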

Results

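Acetylation of lysine 9 on histone H3 (H3K9ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in whole zebrafish embryos at 36 hours post-fertilisation. Embryos without functional sinhcaf, a gene for a subunit of the SIN3 histone deacetylase complex, were compared with wild-type embryos. About 600 embryos were collected, per the labels. The data were 5 lists of called regions, 1 per library: mutant replicates 1, 2 and 3 and wild-type replicates 2 and 3. The mutant libraries held 10958759, 11637663 and 11465310 tags and the wild-type libraries 11297072 and 11155666. Regions are given by their position on GRCz11. The genes at these positions were not analysed here, because no annotation of that build was used.

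The first comparison asked whether embryos without the deacetylase subunit carried more H3K9ac regions or wider ones. The lists held about as many called regions, over about as much of the genome, in both genotypes. Each library was called against its own local background, with no control library. Similar numbers of calls therefore cannot show whether the embryos carried similar amounts of H3K9ac. Read as a check of the lists, the median fold enrichment per list was low, 1.47 to 1.55. Only 10% to 12.4% of the regions in a list carried a caller p-value at or below the cut-off for strong regions. The caller's median −log10 p-value per list was 1.31 to 1.43. Most calls were therefore weak, and the counts by genotype below include them. Whether the weak calls mark H3K9ac was not tested. Called regions covered 42.1% to 43.3% of the chromosomes. Mutant lists held 315069 ± 3100.5 regions (SD, n = 3) and wild-type lists 314682 ± 662 (SD, n = 2). The regions covered 596 ± 3.91 Mb in the mutant and 593 ± 7.71 Mb in the wild type, and their median width was 1089.8 ± 12 bp against 1088 ± 8.49 bp. In exact two-sided permutation tests the p-values were 0.9 for the number, 0.6 for the covered length and 1 for the width. A comparison of 3 libraries with 2 has 10 splits, so its smallest p is 0.1 and no single value of this kind can pass 0.05. Regions wider than 10 kb numbered 2551 ± 52.5 in the mutant and 2715 ± 38.2 in the wild type, with every mutant list below both wild-type lists (exact permutation p = 0.1, the smallest possible, and 0.975 after Benjamini-Hochberg adjustment over 13 measures). Nothing in the labels says that the libraries came from separate clutches, so these p-values measure only the spread between libraries, which may be technical.

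The regions were spread over the chromosomes in nearly the same proportions. Chromosome 4 held 3.99 ± 0.0223% of the chromosomal regions in the mutant (n = 3) and 3.70 ± 0.115% in the wild type (n = 2), and chromosome 22 held 2.33 ± 0.0515% against 2.71 ± 0.0253%. On these chromosomes, on 25 (higher in the mutant) and on 3, 15 and 21 (lower in the mutant), the genotypes did not overlap. That made 6 of 25 chromosomes, and chance gives 20%, or 5 chromosomes. The smallest exact permutation p was 0.1, and 0.625 after adjustment over the 25 chromosomes.

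Lists from the same genotype resembled each other slightly more than lists from different genotypes. Among regions up to 10 kb, the share of bases called in both lists out of those called in either was 0.483 to 0.491 for the 4 pairs within a genotype and 0.467 to 0.476 for the 6 pairs between genotypes. The widths of overlapping regions had rank correlations across regions of 0.440 to 0.459 within and 0.414 to 0.445 between genotypes. Regions are not independent replicates, so no test was made of these correlations.

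The second comparison asked which regions were called in 1 genotype alone. Of 293390 merged regions, 182640 (62.3%) were called in all 5 lists. All 3 mutant lists and neither wild-type list held 2475 of them, and both wild-type lists and no mutant list held 2304. The 9 other splits of the libraries into 3 and 2 gave 1483 to 1974 regions for the set of 3. For the set of 2 they gave 1424 to 2127, so the division by genotype gave the most in both directions. These counts include sequences other than the 25 chromosomes, and on the chromosomes alone the wild-type lead was lost. There the wild-type lists alone held 1532 regions outside and 239 inside long stretches (defined below). Mutant replicates 1 and 2 alone held 1762 and 146. Other settings end this order: with an overlap of 50% of the merged region the wild-type lists alone held 6216, where another split reached 6546, and with the better-scoring 50% of each list the genotypes gave 6112 and 8071, where other splits reached 7248 and 8498. Without wild-type replicate 2 or 3 the wild-type-only count was 12332 or 12743, where other splits reached 12986 and 12894. With regions wider than 10 kb left out, the counts were 3928 for the mutant and 4232 for the wild type, against at most 2393 and 2805 in the other splits. In these counts a place under a wide region of the other genotype is taken as not called there.

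The regions were then divided by whether they touched a long stretch of at least 1 list, meaning a called region or an uncalled gap longer than 10 kb. A median of 4.72% of the bases in one list's wide regions lay in ordinary regions of another list, against 30.8% of the genome. At least 18.7% lay in another list's long gaps. A median of 86.8% lay in another list's wide regions or long gaps, where ordinary regions cannot lie, so the 4.72% follows from this sharing. Inside such stretches, 1591 regions up to 10 kb belonged to the mutant lists alone, against at most 627 in the other splits, and 2048 to the wild-type lists alone, against at most 790. These counts inside long stretches are partly set by leaving out wide regions. With all widths kept, 217 mutant-only regions lay there, where another split reached 256, and 239 wild-type-only regions, against at most 166. Outside them, 1851 belonged to the mutant lists alone, against at most 1597, and 1532 to the wild-type lists alone. In that direction another split reached 1762. The mutant count outside long stretches exceeded all other splits on 11 of 25 chromosomes and the wild-type count on 2, where chance gives 2.5. All chromosomes come from the same 5 libraries and 10 splits, so they are not independent trials and this is not a test.

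**Figure D1:**
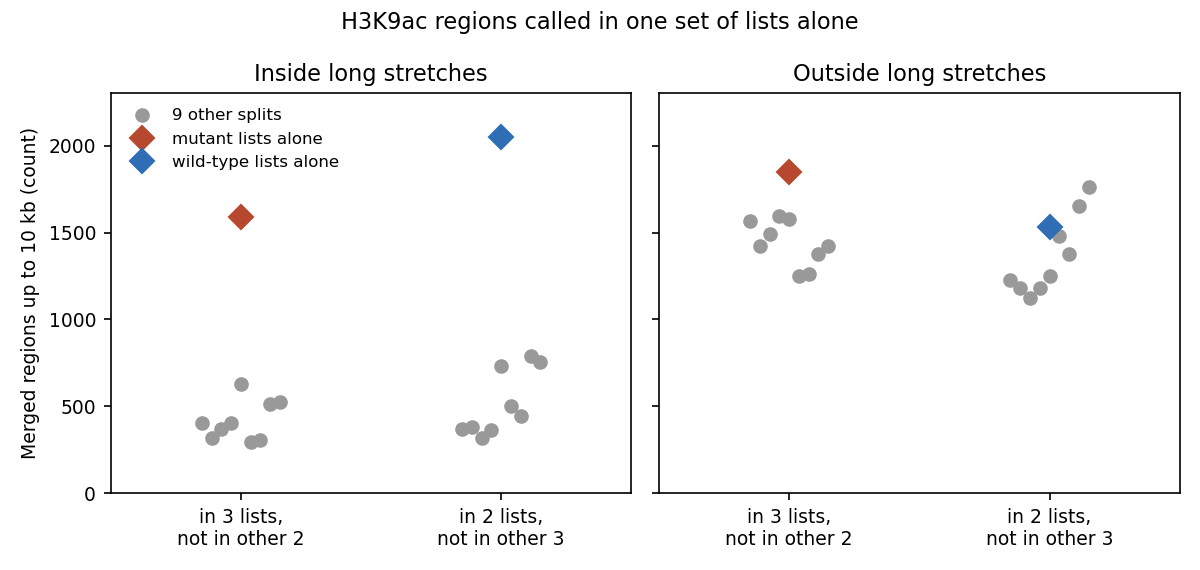
Number of merged regions up to 10 kb called in one set of lists and not in the rest, inside and outside long stretches, with a place under a wide region taken as not called; diamonds are the division by genotype and grey points the 9 other splits of the 5 libraries. Inside long stretches the genotypes gave 1591 and 2048 regions, above every other split, and outside them 1851 and 1532.

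Chromosome 4 held the largest set of mutant-only regions up to 10 kb, at places that mostly touched long stretches. Among 12607 merged regions up to 10 kb on it, 466 (3.70%) were in all 3 mutant lists and in neither wild-type list, against at most 102 in the other splits. Wild-type-only regions numbered 246, against at most 202. With all widths kept, so that a wide region counts as a call, the merged regions on this chromosome included 84 mutant-only regions, against at most 65, and 78 wild-type-only regions, where another split reached 84. Outside long stretches, 66 mutant-only and 64 wild-type-only regions remained on this chromosome, and the other splits reached 59 and 76.

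The long stretches themselves divided by genotype. Shared by all 5 lists were 2954 stretches with 169 Mb, or 12.5% of the 25 chromosomes. A further 565 stretches of at least 5 kb, with 9.17 Mb in all, were long stretches in the 3 mutant lists and in neither wild-type list, and 560, with 8.39 Mb, were so in the wild-type lists alone. Other splits gave at most 187 and 238. Inside the mutant stretches, 77.1% to 81.1% of the bases lay in wide regions of a mutant list and the other 18.9% to 22.9% in its long gaps, while ordinary regions covered 37.3% and 37.1% of the bases in the wild-type lists. Inside the wild-type stretches ordinary regions covered 35.5% to 36.2% in the mutant lists.

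The longest mutant stretches lay on chromosome 3 from 2714809 to 2871122 and on chromosome 24 from 24066819 to 24219816. The first was a single called region in each mutant list and held 41 and 38 regions in the wild-type lists. The second was again a single region in each mutant list and held 49 and 52 regions in the wild type. The longest wild-type stretches lay on chromosome 4 from 49788017 to 49879436, with 1 region in each wild-type list and 25, 30 and 29 in the mutant lists, and on chromosome 14 from 29778886 to 29869589, with 1 region in each wild-type list and 23, 22 and 27 in the mutant lists. Chromosome 4 had 149 of the wild-type stretches, with 2322 kb or 27.7% of their length on 5.81% of the sequence. Of these, 145 started beyond 25 Mb, a boundary chosen after their positions were seen, as did 55 of the 66 mutant stretches on this chromosome. Of its length, 68.0% lies beyond that boundary. This part of chromosome 4, its long arm, is rich in repeats and heterochromatin.

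**Figure D2:**
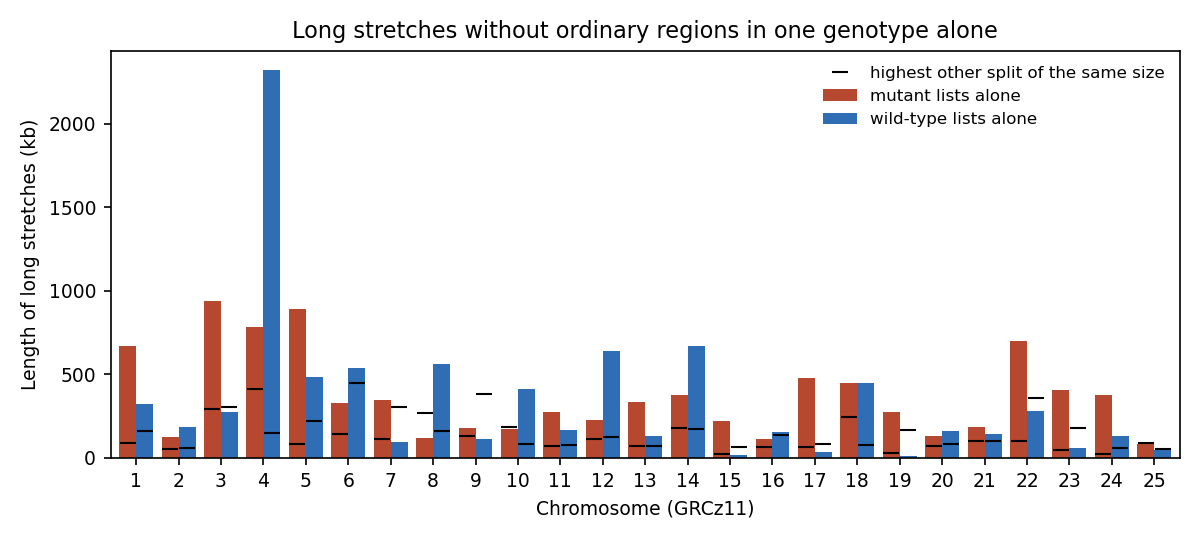
Summed length in kb of the long stretches found in the 3 mutant lists alone or in the 2 wild-type lists alone, by chromosome; black dashes are the highest value of the other splits of the same size. Chromosome 4 stands apart for the wild-type stretches, with 2322 kb, whereas the mutant stretches sum to more on chromosomes 3 (938 kb) and 5 (890.0 kb) than on chromosome 4 (785 kb).

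The third comparison tested the covered length of each 4 kb window on the 25 chromosomes with limma, in place of the covered length at each promoter. At an adjusted p under 0.05, 926 of 333268 windows had more covered bases in the mutant and 963 had fewer. Joined where adjacent and with no overlap between genotypes, they formed 199 stretches with more and 319 with fewer. The longest with more covered bases lay on chromosome 6 from 34452001 to 34684000, chromosome 5 from 37112001 to 37328000, and chromosome 6 from 6424001 to 6612000 and from 6120001 to 6304000. In the leading window of each, 4000 ± 0 bp were covered in the mutant (SD, n = 3) and 0 ± 0 bp in the wild type (n = 2), a difference of 4000 bp with a limma standard error of 276 and an adjusted p of 0.0147. The next by length lay on chromosomes 2, 9, 5, 9, 8, 25, 8 and 13, from 180 down to 116 kb, with the same values.

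Those with fewer covered bases were led by chromosome 17 from 23092001 to 23572000, chromosome 23 from 20964001 to 21420000, chromosome 14 from 8912001 to 9208000 and chromosome 3 from 23136001 to 23336000. Their leading windows had 0 ± 0 bp covered in the mutant and 4000 ± 0 bp in the wild type, a difference with a standard error of 212 and an adjusted p of 0.0110 from limma. The next lay on chromosomes 23, 10, 5, 16, 4, 4, 5 and 14, from 172 down to 84 kb, with the same values. In both directions, the covered bases of the 24 leading windows lay in regions wider than 10 kb. With such regions left out, none of these windows could be tested. The other genotype had no called bases there. In every pair of lists, also within a genotype, 18.65% to 23.65% of the bases in wide regions lay in the other list's long gaps. These windows therefore cannot be read as gained or lost H3K9ac. Of the called windows, 99.6% of those with more and 98.2% of those with fewer lay in long stretches, which hold 24.3% of all windows tested. In a simulation of this comparison with 200 changed windows, limma made 948 false calls, 99.6% of its calls, when residuals were shuffled within a window, and 5245, or 98.5%, when they were drawn with replacement. The adjusted p-values of the named windows are therefore not a measure of their false share.

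The number of calls did not set the genotypes apart from other divisions of the libraries. The genotypes gave 1889 called windows, and the other splits gave 961 to 2377. At an unadjusted p under 0.05 the genotypes gave the most, 21500 windows (6.45%), against 15226 to 18539 (4.57% to 5.56%). With the better-scoring 50% of each list limma called 0 windows (9902 at an unadjusted p under 0.05), and without wild-type replicate 2 it called 5732 with more and 1323 with fewer covered bases. The choice by score says little here too, since the scores may stand beside other regions than their own. For regions up to 10 kb outside long stretches, limma called 0 of 252342 windows, with 14040 (5.56%) at an unadjusted p under 0.05, and the smallest adjusted p was 0.897. At the unadjusted threshold the other splits had 4.44% to 5.19% of windows. In a simulation of that comparison with 200 changed windows, limma recovered 0% of windows shifted by 3000 bp, so a small set of changes was not detectable.

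Alternate contigs, which carry other versions of parts of a chromosome, also divided by genotype. Of 342 alternate contigs with a called region in any list, 47 had one in all 5 lists and 127 in a single list. All mutant lists and no wild-type list had regions on 17, with 9 to 77 regions each, and both wild-type lists and no mutant list on 19, with 7 to 110 regions each. Other splits gave at most 8 and 13. On the contig of chromosome 12 whose regions spanned positions 11554502 to 11719945, the mutant lists had 54, 46 and 54 regions and the wild-type lists had 0. At the same positions on the chromosome itself, regions up to 10 kb covered 0.361 ± 0.625% in the mutant (SD, n = 3) and 39.6 ± 1.41% in the wild type (n = 2). The contig of chromosome 6 at 8951124 to 9267842 had regions in the wild-type lists alone, 80 and 83, and regions up to 10 kb covered 28.0 ± 4.53% of the chromosome there in the mutant and 0 ± 0% in the wild type, whose lists had wide regions over parts of it. Over the 36 contigs of either kind, regions up to 10 kb covered less of the chromosome in the genotype with the contig in 28 (exact two-sided sign test across contigs, p = 0.00119; contigs are not independent replicates). Wide regions are left out of these shares, so a low share does not mean that the chromosome was uncalled. The chromosome 3 contig at 49751071 to 49908827 went the other way, with 13.7 ± 6.94% of the chromosome under regions up to 10 kb in the mutant, which had the contig's regions, and 0 ± 0% in the wild type. Of the length of the mutant stretches, 41.4% lay at positions of alternate contigs with called regions, as did 36.3% for the wild type and 36.1% for the stretches of the other splits.

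**Figure D3:**
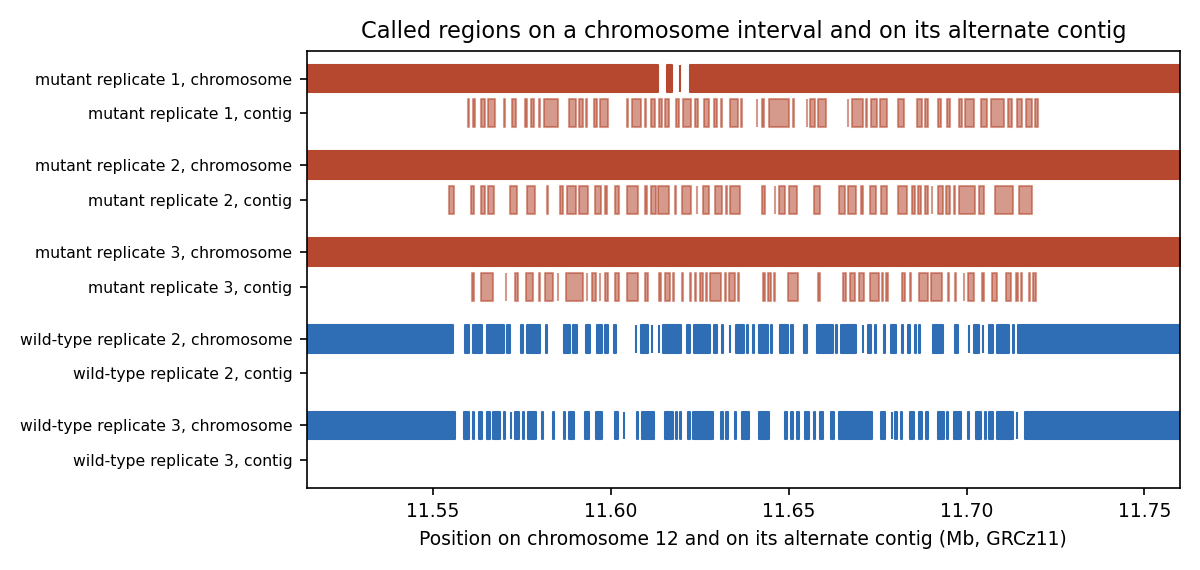
Called regions of each library on chromosome 12 and on its alternate contig, plotted by position in Mb from 11514502 to 11759945; mutant lists are red and wild-type lists blue, with paler bars for the contig. The mutant lists hold 54, 46 and 54 regions on the contig. There the chromosome lies mostly under wide regions in these lists, with short regions and gaps between them in mutant replicate 1. The wild-type lists hold 0 regions on the contig and mainly short regions on the chromosome, with wide regions at both ends of the plot.

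The scores in the lists could be checked for regions that overlap between libraries. Over all chromosomes, their rank correlation between lists fell from a median of 0.365 over the first 100 overlapping regions to 0.0134 over the last 100, while the widths kept medians of 0.420 to 0.481. The scores served to choose regions within a list, in alternatives to the counts above and in 1 of the 13 measures per list, the number of regions with a p-value up to 1e-05.

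**Figure D4:**
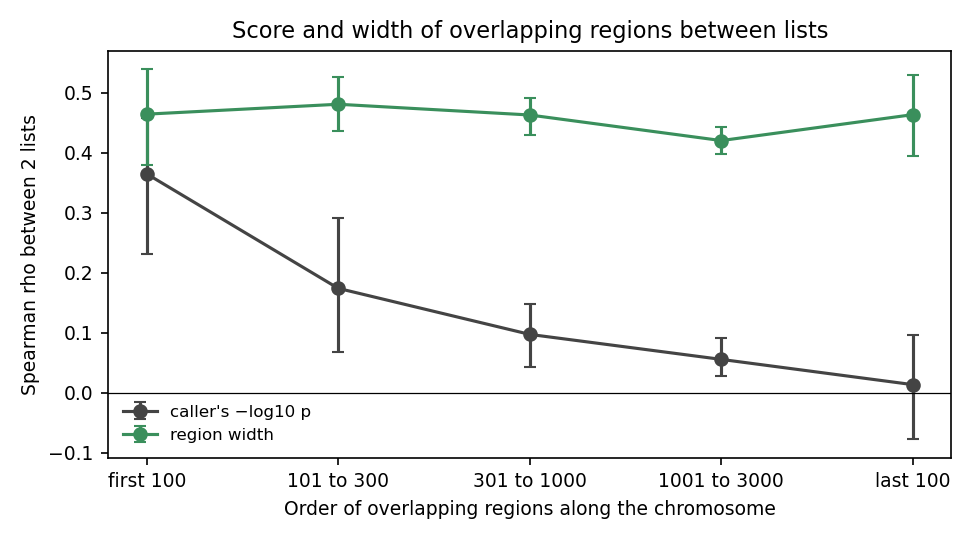
Median rank correlation between pairs of lists, over 250 combinations of pair and chromosome, of the scores and of the widths of overlapping regions, by the order of the regions along a chromosome; bars span the quartiles. Scores fall from 0.365 to 0.0134 and widths stay between 0.420 and 0.481.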

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

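The tests in the weighing of the score columns were chosen only after the results they concern were seen. In mutant replicates 1 and 2, 96.6% and 88.7% of the regions on chromosome 24 carried a p-value of 1e-05 or below. This is a signal in the score column, which entered only 1 of the 13 measures per list and the alternatives that choose regions by score. On the other chromosomes of these lists the share was 6.11% to 13.0% and 7.11% to 16.7%, and on chromosome 24 it was 11.3% in mutant replicate 3 and 8.67% and 7.95% in the wild-type lists. Mutant replicate 1 alone had a called region on the mitochondrial sequence, 1 region of 6635 bp.

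Along each chromosome the scores of overlapping regions lost their rank correlation between lists. The median over 250 combinations of a pair of lists and a chromosome was 0.365 (quartiles 0.232 and 0.458) for the first 100 overlapping regions and 0.0134 (quartiles -0.0777 and 0.0954) for the last 100, while the median correlation of their widths stayed between 0.420 and 0.481. Noise in weak regions as the whole cause is argued against by the first value, 0.365, since noise would act alike at both ends of a chromosome and the quartiles of the ends do not meet. The fall to 0.0134 is consistent with scores written beside other regions than their own, by a shift that grows along the chromosome, and this remains a hypothesis because it was found and tested on the same lists. No biological explanation was tested.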

How the results depend on the processing

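The settings for width, place, p-value and limit, and all settings for long stretches, contigs and chromosome 4, were chosen after seeing the data. Regions in the mutant lists alone and in the wild-type lists alone (2475 and 2304) became 6112 and 8071 with the better-scoring 50% of each list (other splits up to 7248 and 8498), 6905 and 6216 with an overlap of 50% of the merged region (other splits up to 6261 and 6546), 3757 and 3927 for regions up to 20 kb and 3928 and 4232 up to 10 kb. The wild-type count was 3476 up to 50 kb, 1532 outside long stretches and 1485 outside these and the alternate intervals, and for p-values up to 1e-05 the counts were 1137 (other splits up to 754) and 3322 (up to 7894). Mutant-only regions on chromosome 4 fell from 466 to 84 with all widths kept, because wide wild-type regions then count as calls. Long stretches fell to 209 and 206 at a limit of 50 kb, and chromosomes without overlap to 3 in the better-scoring 50% of each list. Windows with more and with fewer covered bases numbered 2361 and 2334 at 2 kb and 1462 and 1150 in limma without trend and robust; limma called 0 and 0 in the better-scoring 50% of each list (9902 at an unadjusted p under 0.05), for regions up to 10 kb (18459) and for those outside long stretches (14040). Of the 24 named windows, 24 kept the call in 9 settings, 0 of the 22 still tested did in the better-scoring 50% of each list, 0 of 24 did with the replicate number as a block (adjusted p = 0.419 in limma, each still differing by 4000 bp), and none was tested once regions above 10 kb were left out. The named windows were chosen for a full difference without spread, so the calls they kept were largely fixed by that choice and are no support. Because the scores may stand beside other regions (correlation 0.0134), the settings that rank by score say little. For p-values up to 1e-05 the wild-type-only count stood beside a median of 1965 in the other splits. The high share of such p-values on chromosome 24 in mutant replicates 1 and 2 enters these counts. Where the construction does not show the cause, the cause was not tested. Depth was 10744373 to 11395261 tags after removal of duplicates, and no value per region carries a depth of its own.

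Leaving out each library in turn gave -1276.5 to 1791.5 for the difference in regions per list, -3.23 to 7.67 Mb for covered length and -4.75 to 7.83 bp for median width, so these directions depend on single libraries. Fewer lists must then agree, which raises the counts, also those of other splits and those expected by chance. There were 4721 to 10712 mutant-only and 4516 to 12743 wild-type-only regions. Leaving out any of the 5 libraries moved both, and with a single wild-type list the wild-type-only count no longer exceeded the other splits. Long stretches numbered 733 to 855 and 694 to 1435, and contigs 19 to 29 and 21 to 51. With a single wild-type list the wild-type stretches were 1435 and 1291, where other splits reached 1147 and 1128. The wild-type contigs were then 47 and 51, where other splits reached 43 and 42. On chromosome 4 lay 697 to 838 mutant-only regions, and 8 to 14 chromosomes were without overlap. Windows called by limma ranged from 1557 to 5732 with more and 1247 to 2453 with fewer covered bases; without a wild-type library the remaining one is assumed to vary like the mutants.

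The lists of numbers 2 and 3 are the same set as without mutant replicate 1. They gave 4721 mutant-only and 4994 wild-type-only regions, 769 and 714 long stretches and 27 and 24 contigs, and no block enters these counts. With the replicate number as a block on these lists, limma called 0 windows with more and 4 with fewer covered bases (16160 at an unadjusted p under 0.05). Samples of 1 number did not deviate together (correlation 0.000893 over all regions and 0.00460 outside long stretches, from 2 pairs), so the numbers are taken as names only. Promoter genes, gene lists, the sinhcaf locus and tag counts per region were not run, because no annotation of GRCz11 and no counts on common regions were used here.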

Other observations

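The tests on depth, alternate contigs, long stretches and wide regions and the splits of the window calls were chosen only after the results they concern were seen; the counts of regions by genotype were planned. More long stretches belonged to 1 genotype alone than to other splits of the libraries. So did regions in the main count, with all lists, all regions and an overlap of 1 bp, though not in every setting. Wild-type-only regions were below another split at an overlap of 50% (6216 against 6546) and outside long stretches (1532 against 1762). They were also below another split on the 25 chromosomes alone, with all widths kept. In the better-scoring 50% of each list both counts were below another split (6112 and 8071 against 7248 and 8498). That setting says little, since the scores may stand beside other regions than their own. Depth is argued against, since the 3 deepest libraries alone shared 126 long stretches against 565 for the mutants. A candidate explanation is that tags went to alternate contigs where a fish line carries that version of the sequence, leaving the chromosome short of tags: 41.4% of the length of the mutant stretches lay at such positions, against at most 10.8% in 100 shifted placements, although stretches of other splits lay there too (36.1%). Outside the positions of contigs with called regions lay 2844 mutant-only regions up to 10 kb, against at most 2008 in other splits. This does not exclude these contigs as the whole cause. Of the 2844, 1033 touched long stretches, where counts are partly set by leaving out wide regions, and 10 splits are too few for a share under 0.05. Loss of sinhcaf and a difference in line between the mutant and wild-type fish cannot be told apart, since both follow the same split; 1811 mutant-only regions remained away from contig positions and long stretches, against at most 1569, and 1485 wild-type-only regions, where another split reached 1720.

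For the long stretches, 1 of 10 splits, the real one, gave as many as 565, and the highest other gave 187; the splits are too few for a share under 0.05. For the windows called by limma, 3 of 10 splits, the real one among them, gave as many as the real 1889, and the highest other gave 2377. This count did not set the genotypes apart, and the splits are again too few for a share under 0.05.

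Regions wider than 10 kb may be tag-poor intervals that the caller bridged. A median of 4.72% of their bases lay in ordinary regions of another list, against 30.8% of the genome. That share cannot decide it, since a median of 86.8% lay in another list's wide regions or long gaps, where ordinary regions cannot lie. Domains shared between lists would give a low share too. Broad acetylated domains as the whole cause are argued against, because at least 18.7% of the bases of wide regions lay in long uncalled gaps of another list in every pair, against at most 5.36% of the genome. Domains as part of the cause stay open, since a median of 67.3% of these bases lay in wide regions of another list, against at most 12.1% of the genome, which shared tag-poor places would give too. Tags at these places were not analysed here.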
